A study of Labroides dimidiatus with 18 samples.

How the data were processed

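RNA came from 18 female bluestreak cleaner wrasse (Labroides dimidiatus), a reef fish that feeds by removing parasites from other fish. Per the labels, whole heads were kept in RNAlater for 3 hours on average and frozen, and the time from capture to death ran from 6 to 28 minutes. Frozen heads were cut into slices of 300 µm, and the second slice from the front of the brain was taken. It held pallial areas Dl and Dm with parts of the septal and striatal territories. Per the labels' protocols, libraries were made by 3' tag sequencing: total RNA was fragmented, cDNA was primed with oligo-dT and amplified by PCR, and the product was sequenced on an Illumina HiSeq instrument. A read therefore comes from the 3' end of a transcript, and its number does not scale with transcript length.

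The authors deposited 2 tables of raw counts per fish, with whole numbers and no normalization. The first holds 28134 gene models with identifiers that begin with Ldim, followed by 5 summary entries for records outside any gene model, ambiguous records, records of low mapping quality, records that did not align and records without a unique alignment. The second holds 26788 transcripts whose identifiers carry the Ensembl prefix of Nile tilapia (Oreochromis niloticus), another fish. Cutadapt 2.8, BWA and SAMtools are named in the submitters' processing notes, without a role. The aligner behind each table, the counting program, the strand setting and the genome build are not given in the sources used here. A count is a read, and removal of PCR copies is not mentioned, so counting intervals and floors below cover counting error only.

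The 5 summary entries name no gene and stayed out of library sizes and tests. Leaving out Watson's Bay fish 19, which is described in the results, they held on average 68.4% of records outside any gene model, 21.7% that did not align, 3.49% of low mapping quality and 0.0102% that were ambiguous (n = 17). The entry for records without a unique alignment was 0 in every fish. Gene models held the remaining 6.44% ± 0.585 (SD, n = 17).

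The files do not pair identifiers with gene names, and no table of names was used here. Gene models are therefore reported by identifier, and their function is not described. The gene lists and marker lists chosen before the data were examined could not be matched to either table, so those tests were not run. The rule chosen before the data were examined made the table of Labroides gene models the main one in that case, and limited the text to 2 identifiers that rose and 2 that fell per comparison. Within that limit, gene models past the threshold were taken by size of the log2 fold change among those with both high-density sites on the same side of both low-density sites. For gene models lower at high density only 1 met this rule, and Ldim_g7292 was added after its values were seen because just 2 were called.

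Counts were analysed in R 4.3.3 with edgeR 4.0.16. Gene models were kept by filterByExpr with a minimum count of 10, which at the median library size means a CPM (count scaled to a common library total) of 238 in at least 8 fish. This left 682 gene models holding 67.0% of gene counts, out of 15257 with at least 1 count. Libraries were scaled by trimmed mean of M values (TMM). Unless stated otherwise, CPM values are relative to the counts in the 682 tested models after this scaling. Differences were tested with edgeR's quasi-likelihood F test (not robust), and p-values were adjusted over the tested models by the Benjamini-Hochberg method with a threshold of 0.05. SE is the fold change divided by the square root of F. Density was tested on all 18 fish with density as the single term. Site contrasts came from a fit with a term for each of the 4 sites. Each density holds 2 sites, and a fish from one site is never of the other density, so density cannot be separated from these particular sites. The biological coefficient of variation was 0.214. The labels describe each library as 1 fish, so p-values measure the spread between fish. All 153 pairs of libraries were checked for duplicates: 0 were identical, and the lowest chi-square per degree of freedom, over gene models with at least 10 counts in the pair, was 1.35, with no pair at p above 0.05. The chi-square allows for counting error only, so it does not exclude 2 libraries made from 1 fish.

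The tests were tried on simulated counts drawn from the real means and library sizes of the 682 models, with 200 changed. For density, 56% of the models changed 1.5-fold, 88% of those changed 2-fold, 100% of those changed 3-fold and 100% of those changed 4-fold were recovered. For The Crest against Clam Gardens the shares were 14%, 54%, 92% and 100%, and for Osprey against Watson's Bay 28%, 62%, 98% and 94%. The 3 simulations gave 175, 133 and 142 calls, against 7, 1 and 0 in the real data. With more calls the adjusted threshold is reached at a larger unadjusted p, so recovery in the real comparisons is probably lower. Differences between sites of the same density were not simulated.

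Per-fish measures were compared between densities by exact two-sided permutation of the difference of means over 43758 regroupings, and among sites by permutation of the variance between sites with 100000 resamples, each adjusted over 8 measures. Alternatives covered scaling by DESeq2 1.42.0 size factors or by all records, no expression filter, a filter of CPM over 5 in 8 fish, DESeq2's own tests, limma 3.58.1 with and without site as a random block, exact permutation, site-weighted and site-summed fits, library size as a covariate, robust dispersion, a threshold of 0.1, the tilapia table, and leaving out each fish and each site. Comparisons with other splits of the fish used up to 100 splits. Permutations and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.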

Results

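Gene expression was profiled in a forebrain slice from 18 female cleaner wrasse caught at 4 sites. The labels class 2 sites as high density, Clam Gardens (n = 3 fish) and The Crest (n = 5), and the other 2 as low density, Osprey (n = 7) and Watson's Bay (n = 3). They do not say what the density counts, and it is taken here as that of cleaner fish. Counts in gene models ranged from 26092 to 42702 per fish at Clam Gardens, from 32548 to 88153 at The Crest and from 29681 to 54648 at Osprey. At Watson's Bay, 2 fish had 51629 and 60465 counts and fish 19 had 3868. These are shallow libraries: 3 counts corresponded to 34.0 CPM over all gene models in the deepest fish, 115 CPM in the shallowest other than fish 19, and 776 CPM in fish 19. The number of gene models with at least 1 count ran from 4399 to 8327 outside fish 19 and was 1374 in it.

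Sites differed in how much of each library fell in gene models. At Clam Gardens 5.87% ± 0.0713 of records were assigned to gene models (SD, n = 3), at The Crest 7.03% ± 0.537 (n = 5), at Osprey 6.41% ± 0.397 (n = 7) and at Watson's Bay 5.55% ± 0.576 (n = 3). Site accounted for 64.1% of the variance in this share (permutation p = 0.00125, adjusted p = 0.01 over 8 measures), and the adjusted permutation p was 0.0409 without fish 19. Counts in tilapia transcripts per 100 counts in Labroides gene models were 87.2 ± 2.13 at Clam Gardens and 67.2 ± 9.95 at The Crest, with Osprey at 77.2 ± 5.82 and Watson's Bay at 86.8 ± 10.6 (permutation p = 0.00791, adjusted p = 0.0316). The share of records with low mapping quality also differed among the sites (adjusted permutation p = 0.0320 for the variance over all of them). It was 3.26% ± 0.122 at Clam Gardens, 3.59% ± 0.115 at The Crest, 3.54% ± 0.131 at Osprey and 3.31% ± 0.205 at Watson's Bay. Between densities no difference in any of the 8 measures exceeded the spread between fish. Counts in gene models averaged 54971 ± 24747 in high-density and 39494 ± 16294 in low-density fish (n = 8 and 10, exact permutation p = 0.129, adjusted p = 0.588).

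Watson's Bay fish 19 differed from all others in its composition. Of its 79053 records, 57.0% did not align (exact Clopper-Pearson 95% interval 56.6 to 57.3), against 19.7% to 24.5% in the other 17 fish. Another 35.0% fell outside gene models and 4.89% (95% interval 4.74 to 5.05) in gene models.

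**Figure D1:**
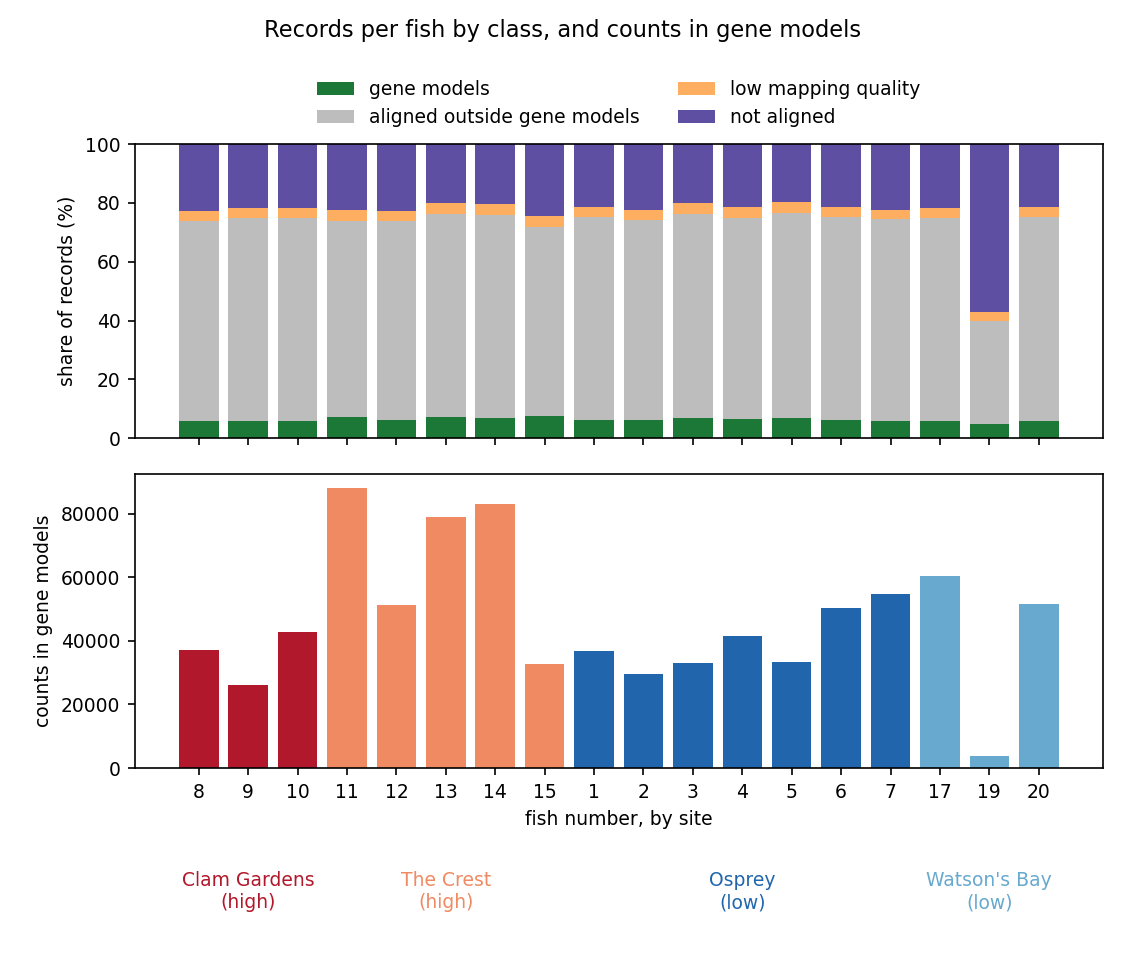
The upper panel shows, for each of 18 fish, the percentage of records assigned to gene models, aligned outside them, of low mapping quality or not aligned, as stacked bars. The lower panel shows counts in gene models on a linear axis, coloured by site, from 3868 in Watson's Bay fish 19 to 88153 in The Crest fish 11.

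The main comparison asked which transcripts differ in this forebrain region between fish from high-density and low-density sites. Of 682 gene models tested, 5 rose and 2 fell at high density. The largest difference was in Ldim_g28127, at 3887 ± 3859 CPM in high-density and 178 ± 298 CPM in low-density fish (SD, n = 8 and 10). Its fitted difference was 18.3-fold (log2 4.19, SE 0.61, 95% interval 2.93 to 5.45, edgeR adjusted p = 0.000117). Ldim_g12384 averaged 9648 ± 7033 CPM at high density and 2275 ± 985 CPM at low density, 3.91-fold higher (log2 1.97, SE 0.30, edgeR adjusted p = 0.000131). Ldim_g414 fell from 3775 ± 1489 CPM at low density to 1837 ± 758 CPM at high density (log2 -1.01, SE 0.23, edgeR adjusted p = 0.0201).

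Both models that rose varied widely among high-density fish. Ldim_g28127 had 2 counts in Clam Gardens fish 9, under the floor of 3 counts, and 670 in The Crest fish 11. In low-density fish it had between 0 and 35 counts, with 0 in 3 of 10 fish (Osprey 3 and 7 and Watson's Bay 19) and fewer than 3 in 6 of 10. Watson's Bay fish 20 alone had 990 CPM. Without it the low-density mean was 87.8 ± 93.0 CPM (n = 9), and Ldim_g28127 fell below the expression filter and was not tested. All 8 high-density fish lay above the low-density median, and 6 of 8 lay above every low-density fish. By site, Ldim_g28127 averaged 2191 ± 2528 CPM at Clam Gardens, 4905 ± 4406 at The Crest, 78.4 ± 78.8 at Osprey and 411 ± 516 at Watson's Bay. For Ldim_g12384, 7 of 8 high-density fish lay above every low-density fish, and the site means were 11193 ± 8214 CPM at Clam Gardens, 8721 ± 7069 at The Crest, 2168 ± 721 at Osprey and 2524 ± 1636 at Watson's Bay. The Watson's Bay mean includes fish 19, with 2 counts, under the floor. Watson's Bay fish 17 and 20 had 3694 and 3225 CPM, close to The Crest fish 14 at 3499 and Clam Gardens fish 8 at 3997. The other 3 models that rose had log2 fold changes of 1.72, 1.75 and 1.81. All 5 had higher means at both high-density sites than at either low-density site.

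Ldim_g414 was below the low-density median in all 8 high-density fish. Its site means were 2248 ± 794 CPM at Clam Gardens, 1591 ± 699 at The Crest, 4236 ± 1501 at Osprey and 2699 ± 857 at Watson's Bay. The other model that fell, Ldim_g7292, was 6129 ± 1760 CPM at high and 10062 ± 3328 CPM at low density (log2 -0.75, SE 0.18, edgeR adjusted p = 0.0341). With all fish it did not separate the sites by density, with 6822 ± 957 CPM at Clam Gardens, 5713 ± 2094 at The Crest, 11465 ± 1812 at Osprey and 6786 ± 4124 at Watson's Bay. The Watson's Bay mean includes fish 19, with 11 counts and 3598 CPM, and Watson's Bay fish 17 and 20 had 11443 and 5319 CPM. Without fish 19 the log2 difference of Ldim_g7292 between densities was -0.82 (edgeR adjusted p = 0.00513). With each site given equal weight, neither Ldim_g414 nor Ldim_g7292 passed (edgeR adjusted p = 0.386 for each), and the 5 that rose did. When 1 fish at a time was left out, Ldim_g7292 stayed called in 6 of 18 fits and Ldim_g414 in 16 of 18.

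Across all tested models the median log2 difference was -0.0037, and 75 (11.0%) had an unadjusted p under 0.05. Higher means at both high-density sites than at both low-density sites were found for 129 models and lower means for 79, together 30.5% of those tested. Random assignments of the fish to sites gave a median of 34.2%, with a range of 21.4% to 43.3% over 99 assignments. Other settings gave more calls, with 21 higher and 2 lower in DESeq2 (4516 models with an adjusted p), 39 and 6 with a filter of CPM over 5 in 8 fish (5938 models), and 81 and 6 without an expression filter (15257 models). With the CPM filter or none, each model's variance was set almost wholly by the trend over all models. The spread of a single model then counted for less than in the main fit. No model passed with limma and site as a random block (38 at unadjusted p under 0.05), with limma and no block (62), or in edgeR without the Osprey fish (48), and exact permutation left Ldim_g12384 alone (adjusted p = 0.0312).

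**Figure D2:**
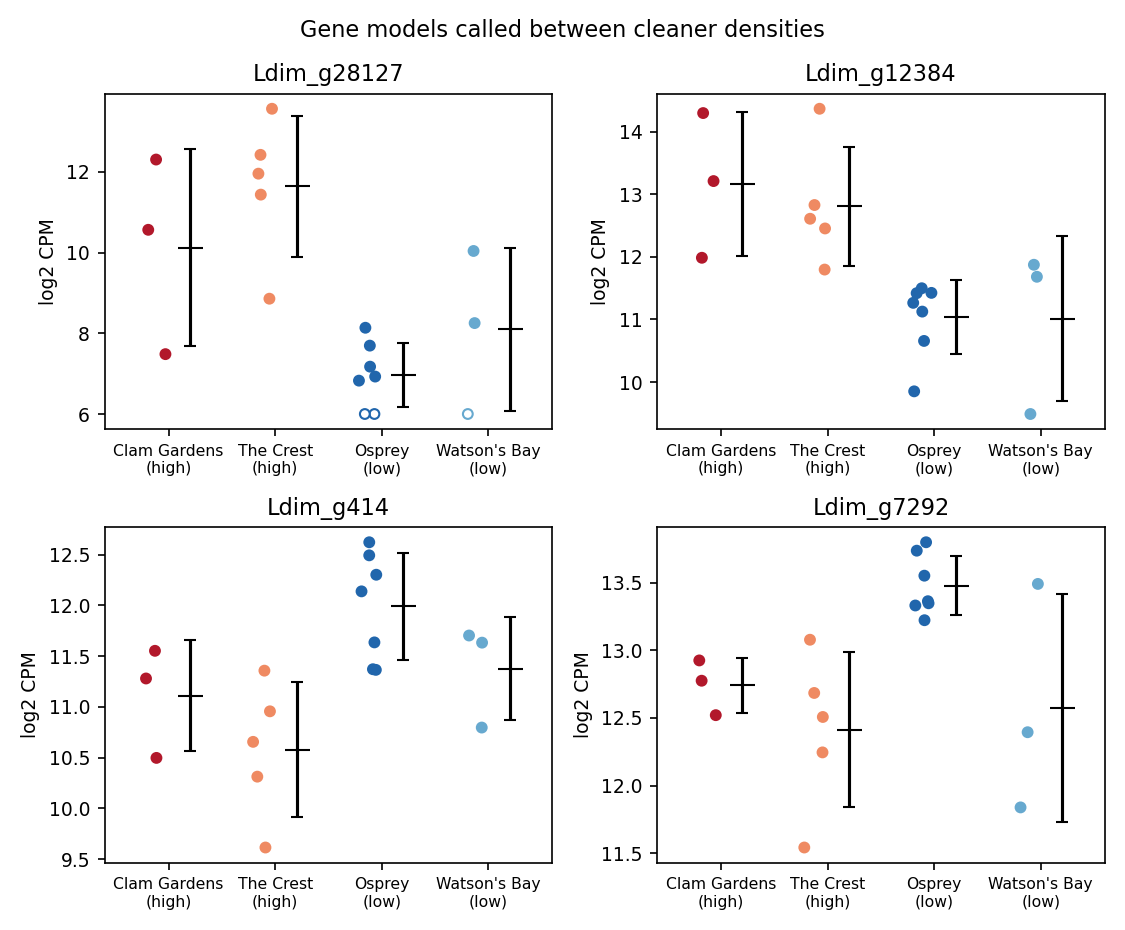
Each panel shows one gene model, with log2 CPM per fish (points, coloured by site) and the mean and SD of each site (black) for 3, 5, 7 and 3 fish. Open points are fish with 0 counts, drawn at the value set by the prior count of 2, and Ldim_g7292 at Watson's Bay overlaps the range of both high-density sites.

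Sites of one density were compared to see how far fish differ where density does not. Between The Crest and Clam Gardens, Ldim_g19793 was the single model that passed. It was higher at The Crest, at 826 ± 170 CPM (SD, n = 5) against 53.8 ± 93.2 CPM at Clam Gardens (n = 3), a log2 difference of 3.78 (SE 0.79, edgeR adjusted p = 0.0381). The Clam Gardens fish had 0, 0 and 4 counts. Osprey fish had 813 ± 325 CPM (n = 7), and Watson's Bay fish had 574 ± 510 CPM with 1, 2 and 43 counts (n = 3). In all, 50 models had an unadjusted p under 0.05. The call ended in 10 of the 18 fits that left out 1 fish, and DESeq2, over 15255 models, called 0 (111 at unadjusted p under 0.05).

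Osprey and Watson's Bay, the low-density pair, had 0 of 682 models past the threshold in edgeR, with 54 at unadjusted p under 0.05, and 0 with DESeq2, with 127 of 15255 models at unadjusted p under 0.05. A difference of 1.5-fold would have been missed for most models at this depth, since 28% of simulated changes of that size were recovered.

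Across the 4 sites 13 models differed, and all 7 density calls were among them. This overlap is partly built in, because the test over the 4 sites includes the density difference in the same counts. The count of 13 became 6 without Osprey fish 2 and 8 without Clam Gardens fish 10 or The Crest fish 11. Comparing single sites across density, The Crest and Osprey differed in 14 models, 8 higher and 6 lower at The Crest. Clam Gardens and Osprey differed in 7, with 6 higher and 1 lower at Clam Gardens. Neither high-density site differed from Watson's Bay in any model in edgeR, with 17 models at unadjusted p under 0.05 for The Crest and 43 for Clam Gardens, and Watson's Bay holds 3 fish including fish 19. When the 4 sites were paired by density and weighted equally, 5 models differed, all higher at high density, and 45 had an unadjusted p under 0.05. The other pairings gave 0 each, with 39 models at unadjusted p under 0.05 for The Crest and Osprey against the rest and 66 for The Crest and Watson's Bay against the rest.

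The counts on tilapia transcripts gave a second reading of the same fish from 509 tested transcripts. ENSONIT00000008027.1 was 7.37-fold higher at high density, at 5175 ± 4551 against 940 ± 1223 CPM (log2 2.88, SE 0.54, edgeR adjusted p = 0.00432, n = 8 and 10). ENSONIT00000014467.1 was 1.97-fold higher, at 3405 ± 1360 against 1606 ± 740 CPM (log2 0.98, SE 0.23, edgeR adjusted p = 0.0418). Both were above the low-density median in all 8 high-density fish. None fell, and 45 transcripts had an unadjusted p under 0.05. The transcripts of this table were not matched to Labroides gene models here.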

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

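The tests of chance and of a shared source among 4 gene models were chosen after the results were seen. The fits with library size as a covariate and with other site pairings were planned, but what they would have to show was set down after their results were seen. Single fish were compared with their group by the gap to the next fish over the group's range, in 56 groups of fish and measures, of which chance would single out about 5%. In 4 groups a fish stood apart.

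Watson's Bay fish 19 accounted for 3 of the 4. Among low-density fish it had the fewest gene models detected, 1374 against 5133 in the next, the lowest share of records outside gene models, 35.0% against 67.8%, and the highest share not aligned, 57.0% against 22.3%. Without it the density comparison again called the 7 models. No explanation of its composition was tested.

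The 7 models called between densities were set against other splits of the 18 fish. Of 100 splits into 8 and 10 fish, 1 gave as many calls, the real one, and the highest other gave 5. A random grouping of fish is thus an unlikely source of a count this high in this fit. The smallest share these splits can give is 1 of 100. Splits were not run for robust dispersion, which called 2 models, or for exact permutation, which called 1. With library size as a covariate 6 of the 7 calls remained. Ldim_g414 was lost, its log2 difference moving from -1.01 to -0.93 (edgeR adjusted p = 0.0925). That fit gives all 18 fish the same slope on library size. For the 6 it therefore argues only against a trend common to all fish, and a link to depth inside each density stays open. Its slope may also rest on Watson's Bay fish 19, at 3868 gene counts against 26092 or more in the others. The fit was not repeated without that fish. Differences among sites that have nothing to do with density stay open. Pairing the sites in the other 2 ways gave at most 1 call against 7 in a 2-group fit, but 3 pairings are too few for a share under 0.05, and density and site cannot be told apart with 2 sites each. Density itself, as the labels name it, stays among the open explanations.

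The Crest fish 15 stood apart in the share of gene counts taken by 4 of the 5 models that rose, at 5.44% against 1.95% in the next The Crest fish. These 4, Ldim_g12384 and the 3 not named in the results, took 2.57% ± 1.81 of gene counts in high-density fish and 0.744% ± 0.303 in low-density fish (SD, n = 8 and 10). Clam Gardens fish 9, at 5.30%, was nearly as high as fish 15. Both were the shallowest high-density libraries, with 26092 and 32548 counts in gene models. The other high-density fish had 0.824% to 2.69%, and low-density fish reached 1.23%. The fifth model that rose, Ldim_g28127, was left out of the set of 4 after its values were seen. Its log2 level against their mean had a Pearson r of -0.101 in high-density fish (exact permutation p = 0.82, adjusted p = 0.875; rho = 0.0476, p = 0.935; r = 0.449 without the 2 farthest) and of 0.914 in low-density fish (permutation p = 7.00e-05, adjusted p = 0.00056; rho = 0.963, p = 7.00e-05; r = 0.949 without the 2 farthest). In low-density fish 6 of its 10 values are under 3 counts, and the difference between densities was not tested, so whether it belongs with the 4 stays open.

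A candidate explanation for the 4 rising together is one shared source, such as a tissue or cell population taken in varying amounts. Because the 4 were chosen among the 5 that rose, the set was tested with that choice repeated in each permutation. The best 4 of the 5, which were these 4, had a mean pairwise Pearson r of 0.525 in the density where it was lower, against permutations of each model among the fish of its density (p = 0.0001, the smallest 10000 permutations give). It was 0.798 without fish 19. The permutations show only that the 4 did not vary independently among fish of the same density. Other sets of 4 models of like abundance were not compared in this way, so the p does not single out a shared source. The p-values that follow do not allow for the choice. Ldim_g12384 followed the mean log2 level of the other 3 in high-density fish (Pearson r = 0.981, exact permutation p = 2.48e-05, the smallest this n allows; Spearman rho = 1, p = 4.96e-05; r = 0.945 without the 2 farthest fish) and in low-density fish (r = 0.726, permutation p = 0.0166; rho = 0.867, p = 0.0019; r = 0.617 without the 2 farthest), with adjusted p = 0.000397 and 0.0443 over 16 relations. Within Osprey alone r was 0.761 (n = 7, exact permutation p = 0.0228, adjusted p = 0.0522) and dropped to 0.273 without the 2 farthest fish, so Pearson's r there rests on them, while Spearman's rho was 0.893 (p = 0.0123). A trend with library size common to all fish is argued against by the covariate fit, in which all 4 stayed called with log2 differences of 1.72 or more. That fit includes fish 19, on which its slope may rest. A link to low depth inside each density stays open. A positive r with library size in either density was set beforehand as the sign against it. The r was -0.731 in high-density fish (exact permutation p = 0.0424, adjusted p = 0.0848; rho = -0.643, p = 0.0962) and 0.436 in low-density fish without fish 19 (exact permutation p = 0.236, adjusted p = 0.315; rho = 0.5, p = 0.178). That sign was met, but the r of 0.436 is within the spread of 9 fish, so it does not settle the question.

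Reads split among near-identical copies of one gene could also tie the 4 together, and this stays open. The shares of the 4 in their sum varied somewhat more than counting error allows, with a chi-square per degree of freedom of 1.88 over 17 fish (resampling p = 0.0001, the smallest 10000 resamples give), which was set beforehand as the sign against it. That sign was met, but it rests on counting error alone. Counts are reads after PCR, and the spread that PCR adds was not measured, so the sign does not settle the question. Random sets of 4 models of like abundance had a median of 3.22, with 9.51% at or under 1.88. The composition of the 4 was thus steadier than in most random sets. However, the 4 had been chosen as models that rose together, and the random sets did not repeat that choice. Steadier shares would follow from it with or without near-identical copies, so the comparison cannot decide. A shared source would keep the composition steady as well. The 3 models not named have identifier numbers spanning 3, with 1 model between them that had 67 counts over the high-density and 30 over the low-density fish. Neither whether the numbers follow genome position nor whether the sequences are alike could be tested here.

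Among the 4 sites, 13 models differed, and 1 of 100 assignments of fish to sites, the real one, gave as many (highest other 4). Chance is thus an unlikely source of the count over all 18 fish, which was 6 without fish 2 and 8 without fish 10 or 11. For The Crest against Clam Gardens, 10 of the 56 splits of the 8 fish gave 1 or more calls (highest other 4), so chance cannot be excluded for its 1 call. For Osprey against Watson's Bay the real count was 0, which any split reaches, so the 100 splits (highest other 2) cannot test chance there.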

How the results depend on the processing

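The scaling to all records, limma without a block and exact permutation were added after the data were seen. The gene list alternatives were not run, as identifiers could not be matched to names. No paired analysis was possible because the labels give the fish no replicate numbers shared between sites. For density (7 calls, 5 higher and 2 lower) the count stayed within 1.5 times of 7 with DESeq2 size factors (7), a threshold of 0.1 (7), library size as a covariate (6), all-record scaling (6, with 5 higher and 1 lower), equal site weights (5) and without The Crest (8, of which 5 were among the 7). It was 87 without an expression filter (81 higher, 6 lower; 15257 models tested), 45 with CPM over 5 in 8 fish (39 and 6; 5938 tested, a laxer filter at this depth), 23 with DESeq2 (21 and 2; 4516 with an adjusted p), 13 without Clam Gardens and 12 without Watson's Bay. All 7 calls were kept in the fits without a filter, with CPM over 5 and without Watson's Bay, and 6 of them with DESeq2 and without Clam Gardens. The count was 3 with counts summed per site, 2 with robust dispersion, 2 in the tilapia table, 1 by exact permutation, and 0 with limma and site as a block, 0 with limma and no block and 0 without Osprey, which leaves 3 low-density fish. With robust dispersion the 7 called models were all among the 23 with a prior of under 5 degrees of freedom, models more variable than the rest. Leaving out 1 fish gave 5 to 9 calls for density, 0 to 2 for The Crest against Clam Gardens, 0 throughout for Osprey against Watson's Bay and 6 to 16 for the 4 sites. The Crest against Clam Gardens lost its call without fish 1, 2, 3, 7, 9, 10, 11, 12, 13 or 15 and had 2 without fish 6 or 19. The 4-site count of 13 dropped to 6 without fish 2 and to 8 without fish 10 or 11.

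Without an expression filter The Crest against Clam Gardens had 14 calls, Osprey against Watson's Bay 5 and the 4 sites 92. In the tilapia table these were 0, 0 and 1, and with DESeq2 0, 0 and 23, over 15255, 15255 and 2815 models with an adjusted p. The cause was not tested. None of the 4 named models of the density comparison changed direction under any alternative in which it was tested. Ldim_g12384 kept its call in 31 of 34, Ldim_g28127 in 29 of 33, Ldim_g414 in 23 of 34 and Ldim_g7292 in 11 of 34. Up to 18 of these left out 1 fish and so reused nearly all the same data. Among them Ldim_g12384 kept its call in 18, Ldim_g28127 in 17, Ldim_g414 in 16 and Ldim_g7292 in 6. Ldim_g12384 lost its call with limma, with or without a block, and without Osprey. Ldim_g28127 lost its call in the same fits and by exact permutation. Over all alternatives, those that lost the call included, the log2 differences ran from 1.49 to 2.2 for Ldim_g12384, 2.84 to 5.66 for Ldim_g28127, -1.19 to -0.45 for Ldim_g414 and -0.91 to -0.19 for Ldim_g7292. Without Watson's Bay fish 20 Ldim_g28127 fell below the filter. At this depth the expression filter left 682 of 15257 detected models. The fits with laxer or no filter called further models, and recovery of changes in the less abundant models was not simulated.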

Other observations

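The comparison of observed with expected counts was chosen after the data were seen. Near-complete loss of a transcript in single fish was rare. Among 837 gene models with at least 15 counts expected in some fish from the median share over all fish but fish 19, 3 models had a fish under 10% of its expected count, in 4 instances. Ldim_g19793, the model that separated The Crest from Clam Gardens, made up 2 of the 4, with 0 counts where 20.4 were expected in Clam Gardens fish 10 and 1 where 24.7 were expected in Watson's Bay fish 20. The other Clam Gardens fish, 8 and 9, had 4 and 0 counts where 17.7 and 12.5 were expected, and Osprey fish had 13 to 34. In the remaining instances Clam Gardens fish 10 had 6 counts of a second model where 114 were expected, and Osprey fish 1 had 0 of another where 24.8 were expected. On tilapia transcripts, 3 of 577 showed such a drop, in 6 instances.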
